A study of Mus musculus with 2 samples.

How the data were processed

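ChIP-seq of H3K4me2 was analysed in 2 biological replicates of mouse embryonic intestine, which form 1 group. The labels name H3K4me2 as the antibody target and a possible control experiment, whose data were not used here. The deposited files were 4 lists of peaks on the mouse assembly mm10, per the file headers. Each replicate's own list was derived from that replicate's alignments and 1 further file that differs between replicates, per the file headers. The pooled list was derived from both alignments and both further files, and the replicated list from the pooled list and both replicates' lists, per the file headers. The aligner, the peak caller, their versions and the rule by which a pooled peak counts as replicated are not given in the sources used here. Each deposited peak carries a fold enrichment (a linear ratio), a −log10 p-value, a −log10 q-value and the offset of its summit, as deposited by the authors. These are the authors' own values per peak and were used only to describe, rank or filter peaks within a list. The lowest −log10 p was 2.03 in replicate 1's list and 2.01 in replicate 2's, and 4.20% and 5.49% of their peaks had a −log10 q under 1.3, so the lists include weak peaks. Peak counts depend on read depth and on that threshold. No read totals were given, so counting intervals were not computed.

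Genes, transcripts and exons came from GENCODE release M21 on GRCm38, the assembly that mm10 names, and sequence from the same assembly. The 21911 protein-coding genes on 21 chromosomes had 93472 annotated TSSs. A promoter peak was a peak overlapping the DNA within 1000 bp of any TSS of the gene. An annotated TSS can lie at or near the promoter of another gene, so a promoter peak may belong to a neighbour. This was not checked for single genes. A peak's location was that of its summit, in the order promoter, exon, intron, intergenic. Covered bp were counted within 5000 bp of the TSS with the most covered bp. They include peaks of neighbouring genes that fall in the window. Distal peaks had the summit over 2500 bp from every protein-coding TSS and were given to the nearest one within 100000 bp. The CpG ratio is observed over expected CpG in the promoter. The test for each list, the 30 gene lists, the alternatives and the rule for named genes were fixed before the data were examined.

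The lists comprised 13 of cell types of the intestine, 10 of other organs, 4 of signalling pathways, 2 general ones and the Hox genes. Ahsp of the erythroid list had no match in the annotation. Shares of genes with a promoter peak were compared with all other protein-coding genes by two-sided Fisher's exact tests. Covered bp and distal peaks were compared with 10000 random lists of the same size (1000 for the distal peaks and CpG matching of the olfactory receptors, and for families of over 100 genes) in two-sided permutation tests, drawn from genes with a promoter peak for covered bp and matched on decile of the gene's nearest-TSS territory for distal peaks. p-values were adjusted by Benjamini-Hochberg over the 30 lists, or over all families with a value in the closing section, with 0.05 as the threshold. Genes near each other can share a peak, so genes within a list are not fully independent. Locations and the overlap of replicates were compared with 1000 random placements of peaks within their chromosomes, which do not avoid unmappable DNA. Random placement therefore understates how often peaks coincide by chance.

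Named genes followed a fixed rule. It took up to 4 examples per list, the 2 members with the most covered bp and the 2 first by name without a promoter peak. It also took the 20 genes with the most covered bp and a promoter peak in both replicates, the 10 genes with the most distal peaks and those tied with the tenth, the 5 strongest distal peaks, and the Hox genes as counts per cluster. Other genes are named where a count is 5 or fewer or as exceptions, chosen after their values were seen. Hoxd12, Hoxb1, Hoxd1, Hoxb9, Hoxd9, Hoxa10 and Hoxa11 are such cases, as is every feature named only in the closing section.

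Alternatives were the promoter window (500 and 2500 bp), 1 TSS per gene, the pooled list, a −log10 q of at least 5, each replicate's own list in place of the replicated list, and lists matched on promoter CpG ratio. For covered bp the window was also set to 2500 and 10000 bp. For distal peaks the limits were also 1000 and 5000 bp from a TSS and 50000 and 500000 bp to the gene, or peaks under 1000 bp apart were joined. For the overlap they were a reciprocal overlap of 50%, the 20000 strongest peaks per list and autosomes only. Alternatives with random placement used 200 placements. The tests were tested on simulated data. With 20-gene lists among 21911 genes, the list test called 0% of 50 unchanged lists, 88.0% of lists lowered to a share of 20% and 80.0% of lists raised to 99%. The permutation test of covered bp called 5.0% of 100 unchanged lists before adjustment and 100% of lists with values multiplied by 2, over 15004 genes. That of distal peaks called 2.0% of 100 unchanged lists and 100% with 2 peaks added per gene, over 21911 genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Peaks on sequences outside the chromosomes (13, 14, 15 and 12 in the lists of replicate 1, replicate 2, both pooled and the replicated peaks) were left out of all comparisons.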

Results

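H3K4me2, histone H3 dimethylated on lysine 4 and found at promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in intestine of B6NCrl mouse embryos at embryonic day 16.5. Tissue was pooled from male and female embryos. There was 1 group with 2 biological replicates, and the label of replicate 2 gives a pool of 41 embryos. The peak list of replicate 1 held 55756 peaks covering 44.96 Mb, and that of replicate 2 held 59701 peaks covering 42.3 Mb. A pooled list from both replicates together held 60075 peaks. The replicated list, which the authors derived from the pooled list and both replicates' lists, held 41323 peaks covering 46.6 Mb, or 1.71% of the chromosomes. The lists carry no read totals, so the depth behind each peak is unknown. With 1 group there was no comparison between groups, and no test over the 2 replicates was run. The tests below compare genes or regions within a peak list. Genes and peaks are not replicates of the tissue. Values refer to the replicated list, and those given as mean ± SD (n = 2) are from the replicates' own lists.

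The first question was which genes carried the mark at their promoters in embryonic intestine. Transcription factors of the gut epithelium and genes of the gut wall carried an H3K4me2 peak at their promoters more often than other genes. All 24 intestinal epithelial transcription factors had a peak within 1000 bp of an annotated transcription start site (TSS), against 68.4% of other protein-coding genes (adjusted p = 0.000857, Fisher's exact test). Gata6, an endoderm regulator on chromosome 18 (11052064 to 11085635, mm10), had 9787 bp covered within 5000 bp of its TSS (9434 ± 465 bp, SD, n = 2). Foxa1, a forkhead factor of endodermal epithelia, had 9069 bp (8184.5 ± 445 bp, SD, n = 2). Of 30 gut mesenchyme genes 29 had a promoter peak (adjusted p = 0.000943, Fisher's exact test), with 9939 bp covered at Foxf1 and 9677 bp at Nkx2-3, both regulators of visceral mesoderm. Col3a1, a fibrillar collagen gene, had no promoter peak but 2104 bp covered within 5000 bp of a TSS. Of the mesenchyme genes 8 are also members of other lists. Smooth muscle genes had a peak in 21 of 22 cases (adjusted p = 0.00861, Fisher's exact test), with 9200 bp covered at the tropomyosin gene Tpm1 and 6541 bp at the filamin gene Flna. The member without one was Kcnmb1, which had a peak in replicate 2's own list. In replicate 1's own list the smooth muscle share was 90.9% and missed the threshold (adjusted p = 0.0546, Fisher's exact test). Intestinal stem and progenitor genes had a peak in 18 of 19 cases (adjusted p = 0.0196, Fisher's exact test), among them Lrig1 with 6878 bp and Myc with 6165 bp. Olfm4, a crypt stem cell marker, had none in the replicated list although each replicate's own list held a peak at its promoter.

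The lists of other cell types of the intestine differed widely. Cell types were not separated, so a list's share may depend on how common its cell type was at this stage. Members may also carry the mark in other cell types. Neither was tested. Of 26 enterocyte genes, which serve absorption, 22 (84.6%; 90.4% ± 2.72, SD, n = 2) had a promoter peak. This did not pass the test against all other genes (adjusted p = 0.119, Fisher's exact test), but it did in replicate 2's own list, in the pooled list and within 2500 bp of a TSS (adjusted p = 0.0140, 0.00424 and 0.0168, Fisher's exact test). Anpep, which encodes a brush border peptidase, had 8017 bp covered and Dgat2, an enzyme of triglyceride synthesis, had 5105 bp. Ace2 and Apoa4 had no promoter peak in the replicated list, but Ace2 had one in replicate 2's own list and Apoa4 in replicate 1's. Within 5000 bp of a TSS of Apoa4, 1783 bp were covered. Enteric nervous system genes had a peak in 21 of 24 cases, among them Zeb2 (8674 bp covered) and Hand2 (7397 bp), whereas Phox2b and Plp1 had none. All 6 genes of interstitial cells of Cajal, the pacemaker cells of the gut, had a peak, with 4822 bp covered at Etv1 and 3955 bp at Gjc1. Endothelial genes had a peak in 16 of 22 cases, with 5533 bp covered at Prox1 and 3745 bp at Egfl7 and no promoter peak at Cdh5 or Emcn. Enteroendocrine and tuft cell genes had a peak in 17 of 24 cases, including Sct and Insm1 but not Gcg or Gfi1b. Mesothelial genes had one in 6 of 10 cases, including Krt19 and Wt1 but not Msln or, outside replicate 1's own list, Gpm6a. Goblet and Paneth cell genes had one in 9 of 18 cases, including Gfi1 and Muc13 but not Ang4 or Clca1. None of these 6 lists passed the test, although the enteric nervous system list did within 2500 bp of a TSS (adjusted p = 0.0352, Fisher's exact test). Immune cell genes lay below other genes with 5 of 22 (adjusted p = 8.05e-05, Fisher's exact test). Foxp3 and Rorc had the most covered bp of that list, 2762 and 2291, and Adgre1 and Aif1 had no peak. At Foxp3 the promoter CpG ratio was 0.674, against a list median of 0.213. Whether its peak belongs to a neighbouring promoter was not checked. Of 17 erythroid genes 6 had a peak (adjusted p = 0.0116, Fisher's exact test), including Tfrc and Epor but not Alas2 or Epb42.

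Signalling genes carried promoter peaks almost throughout. Every gene of the Hedgehog (15), Wnt (38), Notch (20) and BMP (20) lists had one, with adjusted p-values of 0.00861, 1.2e-05, 0.00243 and 0.00243 in Fisher's exact tests. The members with the most covered bp were Ptch1 (9954 bp), which encodes the Hedgehog receptor, and Gli3 (5098 bp), then Wnt5a (7209 bp) and Fzd5 (7069 bp), Hes1 (8127 bp) and Dll1 (7142 bp), and Id2 (9279 bp) and Smad7 (8857 bp). All 23 housekeeping genes had a peak (adjusted p = 0.00121, Fisher's exact test), led by Rps18 with 8126 bp and Rpl13a with 7227 bp. So did all 24 cell cycle genes (adjusted p = 0.000857, Fisher's exact test), led by Ccnd2 with 9060 bp and Ccnd1 with 6695 bp.

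Genes of other organs mostly lacked the mark, except those of brain and kidney. With matching on promoter CpG ratio, given below, only the germ cell and olfactory receptor lists stayed below. Peaks were found at the promoters of 4 of 20 liver genes (adjusted p = 8.05e-05, Fisher's exact test), with 3542 bp covered at Apoh and 1561 bp at Ttr and none within 1000 bp of Afp or Ahsg. They were found at 8 of 20 skeletal muscle genes (adjusted p = 0.0208, Fisher's exact test), including Mylpf and Actn3 but not Cacna1s or Chrna1. Epidermal genes had 6 of 18 (adjusted p = 0.00727, Fisher's exact test), including Sfn and Krt10 but not Casp14 or Cdsn. Lung genes had 4 of 14 (adjusted p = 0.00583, Fisher's exact test), including Slc34a2 and Abca3 but not Ager or Lamp3. Pancreas genes had 7 of 17 (adjusted p = 0.0485, Fisher's exact test), including Pdx1 and Nkx6-1 but not Cel or Cela2a. Germ cell genes had 3 of 20 (adjusted p = 1.2e-05, Fisher's exact test), including Tdrd1 and Dppa3 but not Ddx4 or Figla. Olfactory receptor genes had 4 of 1134 (0.353%; 0.529% ± 0.125, SD, n = 2), with Olfr56 and Olfr94 the most covered and Olfr1 and Olfr10 among those without, and they also lay below other genes. Of the genes of other organs named as lacking a peak, Afp, Casp14 and Ager had one in replicate 1's own list, and Cdsn and Gfap in replicate 2's. Within 2500 bp of a TSS the skeletal muscle and lung lists, at −19.7 and −26.9 percentage points against other genes, no longer passed (adjusted p = 0.115 and 0.0567, Fisher's exact test). In replicate 1's own list the epidermal and pancreas lists, at −24.7 and −22.1 percentage points, missed the threshold (adjusted p = 0.0561 and 0.0876, Fisher's exact test). Cardiac muscle genes (9 of 19, with Myl7 and Myl3 but not Ankrd1 or Mybpc3), kidney genes (9 of 16, with Sall1 and Lhx1 but not Aqp2 or Cdh16) and brain genes (20 of 24, with Pou3f2 and Emx1 but not Gfap or Neurod6) did not pass the test against other genes. The cardiac list passed, below other genes, within 500 bp of a TSS and with a −log10 q of at least 5 (adjusted p = 0.0365 and 0.0361, Fisher's exact test). The promoter CpG ratio was 0.738 at Apoh against a liver median of 0.215, and 0.55 at Myl3 against a cardiac median of 0.252. The record of Olfr56 runs from 48978889 to 49135387. Whether the peaks at these genes belong to neighbouring promoters was not checked.

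Over all 13 intestine lists together, 200 of 264 genes (75.8%; 77.3% ± 1.61, SD, n = 2) had a promoter peak. Over the lists of other organs without olfactory receptors it was 70 of 168 (41.7%; 43.2% ± 0.421, SD, n = 2). The odds ratio was 4.38 (two-sided p = 1.21e-12, Fisher's exact test). The lists were not matched on the kind of gene, such as transcription factors, so organ and kind of gene cannot be told apart here. Shares of single lists ran from 22.7% for immune cell genes to 100% in the intestine class. In these lists of other organs they ran from 15.0% for germ cell genes to 83.3% for brain genes.

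**Figure D1:**
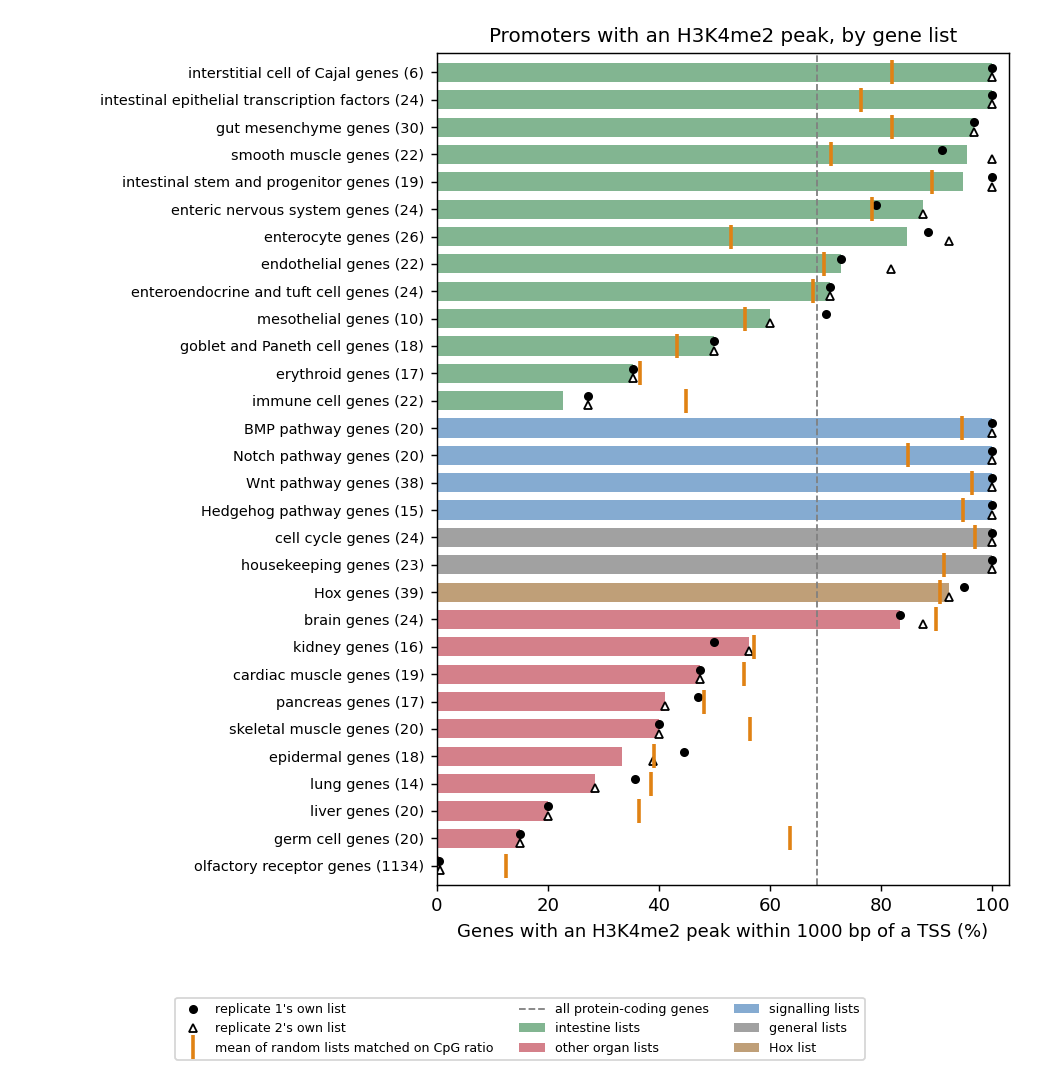
Share of each list's genes with an H3K4me2 peak within 1000 bp of a TSS, in percent. Bars are the replicated list, circles and triangles the own lists of replicates 1 and 2, orange ticks the mean of random lists matched on promoter CpG ratio, and the dashed line all protein-coding genes (68.5%); the number of genes stands in brackets. Bars of the intestine lists run from 22.7% for immune cell genes to 100%, and those of other organs from 0.353% to 83.3% for brain genes.

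Across the genome 15004 of 21911 protein-coding genes (68.5%; 69.1% ± 0.00323, SD, n = 2) had a promoter peak. The share followed the CpG content of the promoter, from 5.70% of genes in the lowest decile of the observed/expected CpG ratio to 99.5% in the highest. Against random lists matched on that ratio, intestinal epithelial transcription factors (100% against a mean of 76.3%; adjusted p = 0.002, permutation test) and enterocyte genes (84.6% against 53.1%; adjusted p = 0.002, permutation test) lay above. Smooth muscle genes (95.5% against 71.0%; adjusted p = 0.0252, permutation test) and gut mesenchyme genes (96.7% against 82.0%; adjusted p = 0.0280, permutation test) did too. Germ cell genes (15.0% against 63.6%; adjusted p = 0.002, permutation test) and olfactory receptor genes (0.353% against 12.5%; adjusted p = 0.0150, permutation test) lay below. The ratio was taken at 1 TSS per gene, whereas a peak at any TSS counted. Before matching, the enterocyte difference from other genes was 16.2 percentage points. With 1 TSS per gene it was 8.23 (adjusted p = 0.485, Fisher's exact test). The calls for 15 lists ended with matching on CpG ratio. Of these, Notch genes (100% against 84.9%) and immune genes (22.7% against 44.9%) lay nearest the threshold (adjusted p = 0.0705 for both, permutation test), followed by housekeeping genes (100% against 91.4%; adjusted p = 0.289), liver genes (4 of 20 against 36.5%; adjusted p = 0.297) and skeletal muscle genes (40.0% against 56.5%; adjusted p = 0.297). Cell cycle, Wnt, Hedgehog and BMP genes were at 100% against 96.97%, 96.4%, 94.7% and 94.6%. No share above 100% is possible, so the matched test could not have called these 4 lists, the housekeeping list or the Notch list above. The other 6 lists were stem and progenitor (94.7% against 89.2%), Hox (92.3% against 90.5%), erythroid (35.3% against 36.5%), epidermal (33.3% against 39.2%), lung (28.6% against 38.6%) and pancreas (41.2% against 48.2%). The difference between intestine and other organ lists held within CpG deciles (odds ratio 5.69; p = 2e-05, permutation test, the smallest p its resamples can give). Promoter peaks were found for 69.8% of autosomal and 51.9% of X-linked protein-coding genes, and for 1 of 183 on the Y chromosome. Of 5847 lincRNA genes, each taken at 1 TSS, 18.1% had one. The share of protein-coding genes with 1 TSS per gene was 64.9%. Of the 5139 lincRNA genes over 5000 bp from a protein-coding TSS, 12.3% had one.

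Within 5000 bp of the TSS, epithelial transcription factors and Hox genes had the highest median H3K4me2 coverage of the 30 lists. Within 2500 bp the Hox excess over random lists was 1160 bp, below that of gut mesenchyme genes (1464 bp), housekeeping genes (1305 bp) and Hedgehog genes (1277 bp). The narrower window also lowered the excess of epithelial transcription factors from 3264 to 1632 bp, of smooth muscle genes from 2117 to 695 bp, of Notch genes from 1838 to 898 bp and of BMP genes from 1752 to 990 bp. Covered bp included peaks of neighbouring genes in the window, and random lists were matched on neither gene density nor number of TSSs. Wider and narrower below therefore mean more and fewer covered bp. Among genes with a promoter peak, a median of 2330 bp (2163 ± 98.99 bp, SD, n = 2) of the 10001 bp centred on the TSS was covered. The median reached 5608 bp for intestinal epithelial transcription factors (5204 ± 249 bp, SD, n = 2) and 5397 bp for Hox genes (4750.5 ± 616 bp, SD, n = 2). It was 4464 bp for smooth muscle, 4248 bp for Hedgehog, 4188 bp for Notch, 4115 bp for gut mesenchyme and 4024 bp for housekeeping genes, and each of these 7 lists had an adjusted p of 0.000857 in the permutation test against random lists of the same size. That value rests on 0.0002, the smallest p that the permutation test can give before adjustment. The Hox p cannot be read as a test, since windows of neighbouring Hox genes overlap and 1 peak can count for several of them. BMP genes (4098.5 bp; adjusted p = 0.0015), cell cycle genes (3346 bp; adjusted p = 0.00545), stem and progenitor genes (3324.5 bp; adjusted p = 0.0210) and Wnt genes (2958 bp; adjusted p = 0.0196) were also wider in the permutation test. With the pooled list the stem and progenitor excess over random lists was 810 bp, against 967 bp in the replicated list, and missed the threshold (adjusted p = 0.0536, permutation test). Enterocyte genes had a median of 3390 bp (adjusted p = 0.0055, permutation test), but the excess over random lists fell from 1043 bp to 461 bp in replicate 2's own list and 165 bp in replicate 1's, and neither passed the permutation test (adjusted p = 0.125 and 0.588), nor did the list within 2500 bp (adjusted p = 0.110). The smooth muscle excess was 2117 bp and 808 bp in replicate 2's own list. Enteroendocrine and tuft cell genes (1371 bp; adjusted p = 0.003), skeletal muscle genes (1339.5 bp; adjusted p = 0.0180), the 3 germ cell genes with a peak (750.0 bp; adjusted p = 0.0166) and the 4 olfactory receptor genes (788 bp; adjusted p = 0.002) were narrower in the permutation test. The other 14 lists did not pass it, with medians from 1464 bp for liver to 2722 bp for interstitial cells of Cajal. Of these, liver genes were narrower with the pooled list and cardiac muscle genes within 2500 bp (adjusted p = 0.0060 and 0.0020, permutation test). With matching on CpG ratio the skeletal muscle difference went from −1038 to −843 bp and the olfactory receptor one from −1670 to −1157 bp, and both missed the threshold (adjusted p = 0.0620 and 0.0896, permutation test). Within 10000 bp the skeletal muscle difference was −655 bp (adjusted p = 0.453, permutation test). The enteric nervous system list, at 2025 bp, was narrower in replicate 2's own list (adjusted p = 0.0197, permutation test).

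**Figure D2:**
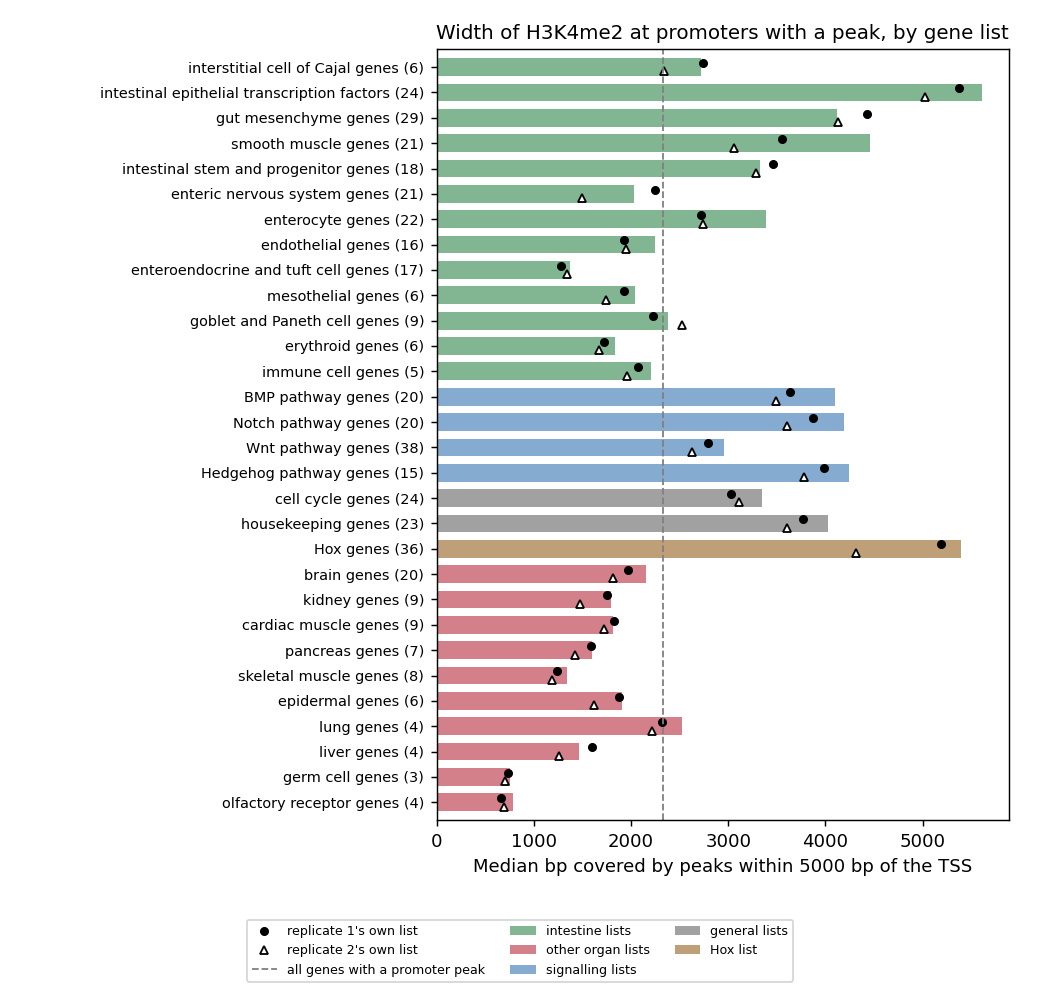
Median bp covered by H3K4me2 peaks within 5000 bp of the TSS, over each list's genes with a promoter peak (their number in brackets). Bars are the replicated list, circles and triangles the own lists of replicates 1 and 2, and the dashed line all genes with a promoter peak (2330 bp). Epithelial transcription factors (5608 bp) and Hox genes (5397 bp) have the longest bars.

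The 20 genes with the most covered bp that had a promoter peak in both replicates ranged from 9320 bp at Rpl18 to 10001 bp at Hoxb4. They held Hoxb3, Hoxb5 and Hoxa2, and Meis1 (9874 bp) and Meis2 (9948 bp), which encode partners of Hox proteins. Ptch1, Foxf1, Nkx2-3 and Gata6 were among them, as were the chromatin genes Kdm6b (9944 bp), Zmynd8 (9486 bp) and Bahcc1 (9585 bp). The remaining members were Tshz1, Zadh2, Zbtb7b, Tnrc18, Hic1 and Zfp503. Zadh2 and Tshz1 lie side by side on chromosome 18, so their windows overlap.

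Peaks far from protein-coding promoters were frequent around epithelial transcription factors and signalling genes. Of the replicated peaks on chromosomes, 17211 (41.7%) had their summit over 2500 bp from every protein-coding TSS. They were narrower than peaks with the summit within 1000 bp of one (median 567 against 1285.5 bp) and weaker (median fold enrichment, the authors' value per peak, 5.08 against 16.9). Each intestinal epithelial transcription factor had on average 5.33 such peaks (6.96 ± 0.825, SD, n = 2), against 1.13 in random lists matched on the length of DNA nearest to the gene (adjusted p = 0.002, permutation test). The random lists were drawn from all protein-coding genes, with or without a promoter peak. The excess of a list with a peak at nearly every promoter was thus not measured against genes that also have one. BMP genes had 3.75 against 1.23 and gut mesenchyme genes 3.13 against 1.27 (adjusted p = 0.002 for both, permutation test). Means above random lists were also found in the permutation test for stem and progenitor genes (3.16; adjusted p = 0.00733), Hedgehog genes (2.87; adjusted p = 0.0305), Notch genes (2.45; adjusted p = 0.0048) and Wnt genes (2.34; adjusted p = 0.0070). The same held for enterocyte genes (2.08; adjusted p = 0.00733), smooth muscle genes (2.05; adjusted p = 0.0108) and Hox genes (0.974; adjusted p = 0.0030, permutation test). Olfactory receptor genes lay below, with 0.0282 against 0.306 (adjusted p = 0.00733, permutation test). The other 19 lists did not pass. The own lists of replicates 1 and 2 held 26095 and 27342 distal peaks, and the excess over random lists was larger there for the 10 lists above, as for smooth muscle genes with 2.19 and 2.36 against 1.28. Housekeeping genes passed in the own list of either replicate (adjusted p = 0.0150 in replicate 2 and 0.0351 in replicate 1, permutation test), and enteric nervous system genes in replicate 1's (adjusted p = 0.0240, permutation test). With peaks under 1000 bp apart joined, the excess over random lists fell from 4.20 to 1.87 peaks per gene for epithelial transcription factors, from 1.92 to 1.20 for stem and progenitor genes, from 1.28 to 0.701 for enterocyte genes and from 0.748 to 0.441 for Hox genes, and these 4 lists still passed the permutation test. It fell from 1.28 to 0.603 for smooth muscle, from 1.86 to 0.720 for mesenchyme and from 1.73 to 0.736 for Hedgehog genes, and these calls ended (adjusted p = 0.0960, 0.0706 and 0.197, permutation test), while brain, skeletal muscle and housekeeping genes passed above random lists (adjusted p = 0.0318, 0.0318 and 0.0376, permutation test). Housekeeping genes also passed with peaks over 1000 bp from a TSS (adjusted p = 0.00545, permutation test). Counted over 5000 bp from a TSS, the smooth muscle and Hedgehog excesses were 0.657 and 1.11 and the calls ended too (adjusted p = 0.124 and 0.118, permutation test). The excess fell to 1.01 for mesenchyme genes, which passed narrowly (adjusted p = 0.049995, permutation test), to 1.09 for Notch genes and to 0.466 for Hox genes, and the olfactory receptor difference went from −0.277 to −0.182. Over 1000 bp from a TSS it was 2.16 for enterocyte, 1.99 for smooth muscle and 1.26 for Hox genes. With peaks up to 500000 bp from the gene the Hedgehog excess was 1.77, no smaller than the main value, but missed the threshold (adjusted p = 0.0567, permutation test).

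The genes with the most distal peaks were Gse1 (26 peaks), Zfp608 (19), Prdm16 and Rere (18 each), Ahdc1 and Maml3 (17 each), Chd2, Gata4 and Sept9 (16 each), followed by Foxp1, Sh3pxd2a, Smad7 and Zfp217, tied at 15. Gata4 encodes a zinc finger factor of the proximal gut, and Maml3 a Notch coactivator. The strongest distal peak, with a fold enrichment of 51.7, lay on chromosome 9 at 77654897 to 77656232 in an exon of Klhl31, 19022 bp from the nearest protein-coding TSS. The next were on chromosome 5 at 106573879 to 106575260 (50.6), outside protein-coding genes and 193 bp from the TSS of the non-coding gene Gm28050, and on chromosome 4 at 123685851 to 123687885 (49.6), 2699 bp from a TSS of Macf1. Peaks on chromosome 16 at 96158586 to 96160117, in an exon of Lca5l, and on chromosome 2 at 21141200 to 21142760, 63181 bp from Enkur, both had a fold enrichment of 48.1.

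Coverage of the Hox clusters, whose genes pattern the body axis and are numbered by paralogue group from anterior to posterior, differed between their anterior and posterior parts. A promoter peak was found at 11 of 11 genes of cluster A, 10 of 10 of cluster B, 7 of 9 of cluster C and 8 of 9 of cluster D. Together 36 of 39 had one (adjusted p = 0.00231 against other genes, Fisher's exact test), and the genes without were Hoxc11, Hoxd12 and Hoxc12, which had one in replicate 1's own list. Within 1000 bp of the TSS the median covered length was 1899 bp for the 27 genes of groups 1 to 9 and 836 bp for the 12 genes of groups 10 to 13. The records of Hoxd3 and Hoxd4 start at 74711927 and 74711929. Both genes had 1899 bp, so the same peaks were counted for both. Within 5000 bp, where windows of neighbouring genes overlap, the medians were 6609 and 1023.5 bp. By cluster they were 7961.5 and 1994 bp in A, 8057 and 640.0 bp in B (1 posterior gene), 3629 and 361.5 bp in C, and 3162 and 1341 bp in D. The ranges overlapped. Among groups 1 to 9, Hoxb1, Hoxd1, Hoxb9 and Hoxd9 had 1121, 1453, 1817 and 2042 bp, and among groups 10 to 13, Hoxa10 and Hoxa11 had 5494 and 1994 bp. The widest peak of the list, 22998 bp on chromosome 11 from 96301603 to 96324600, spanned TSSs of Hoxb3, Hoxb4 and Hoxb5.

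**Figure D3:**
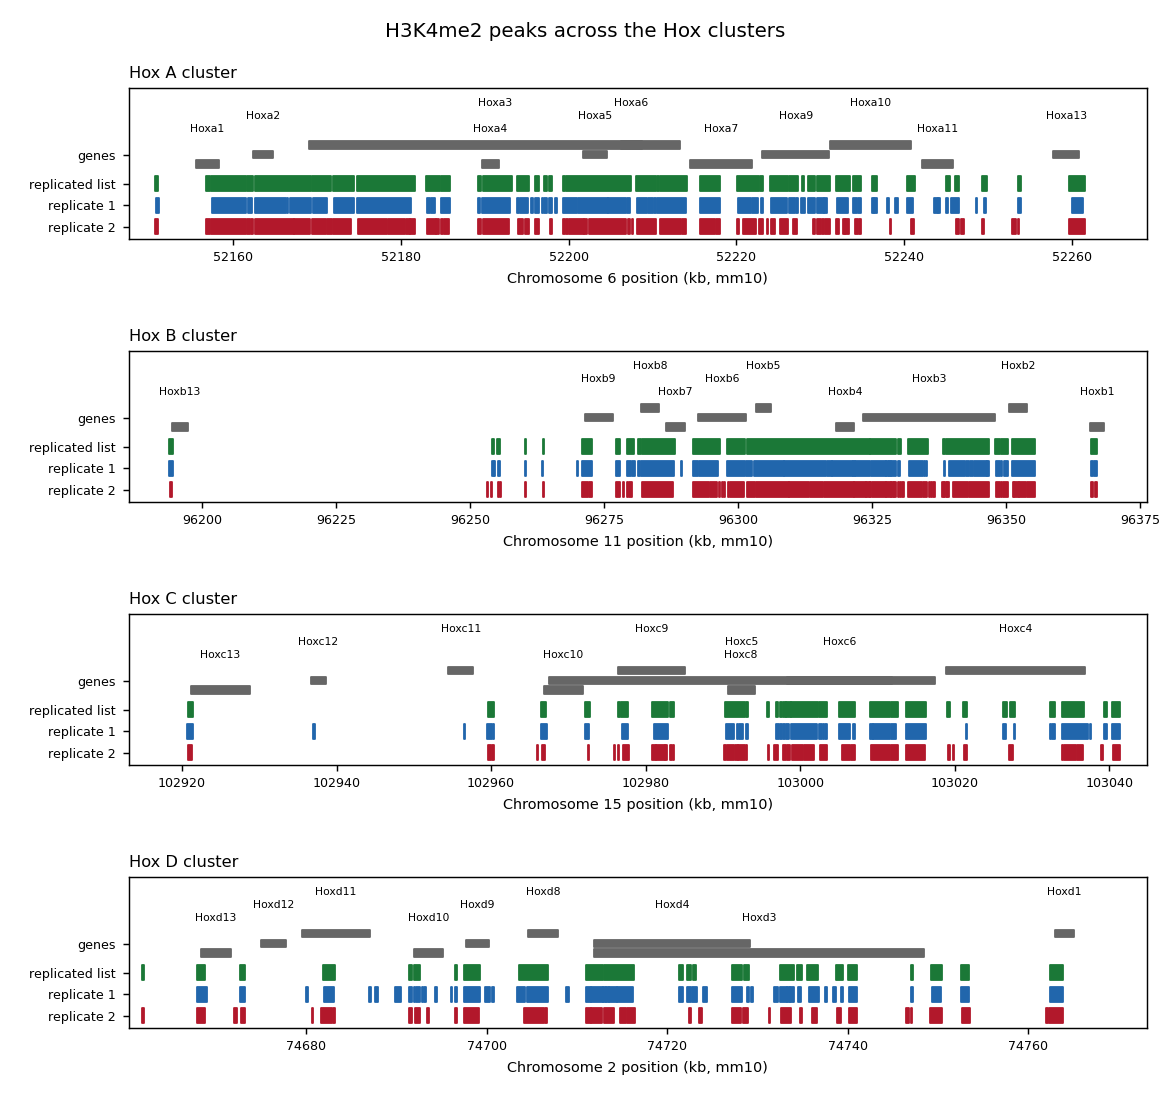
Peaks across the Hox A, B, C and D clusters (chromosomes 6, 11, 15 and 2, position in kb, mm10), with gene records in grey on staggered rows. Green, blue and red bars are the peaks of the replicated list and of the own lists of replicates 1 and 2. Peaks are mostly dense from groups 1 to 9 and sparse around groups 10 to 13. Of the anterior groups, Hoxb1, Hoxb9 and Hoxd1 also have little coverage, and of the posterior groups Hoxa10 has 5494 bp covered within 5000 bp of a TSS.

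By the position of the summit, 48.5% of replicated peaks lay within 1000 bp of a protein-coding TSS, 12.2 times the 3.96% of randomly placed peaks. Exons outside promoters held 3.93% against 2.79%, introns 23.9% against 34.5% and intergenic DNA 23.7% against 58.7%. Each share differed from random placement (p = 0.002, permutation test, two-sided, the smallest it can give). In the replicates' own lists promoters held 41.1% ± 0.168 and introns 29.5% ± 0.340 (SD, n = 2). With promoters extended to 2500 bp the exon share was 1.05 times the random one and no longer passed (p = 0.139, permutation test).

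The comparison between replicates asked how far their peak lists overlapped. Of replicate 1's peaks 74.7% overlapped a peak of replicate 2 by at least 1 bp, and 76.0% of replicate 2's overlapped one of replicate 1, against a mean of 3.14% for replicate 1's peaks placed at random. The Jaccard index of covered bp was 0.695 against 0.00913 (p = 0.000999, one-sided permutation test, the smallest it can give). Strong peaks were shared almost throughout. Ranked by the authors' p-value, the 27872 stronger peaks of replicate 1 overlapped replicate 2 in 99.1% of cases and the 27871 weaker ones in 50.4%, and in replicate 2 the shares were 98.9% and 53.1%. Over 38125 shared regions the fold enrichments had a Spearman correlation of 0.883, across regions that are not independent replicates.

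**Figure D4:**
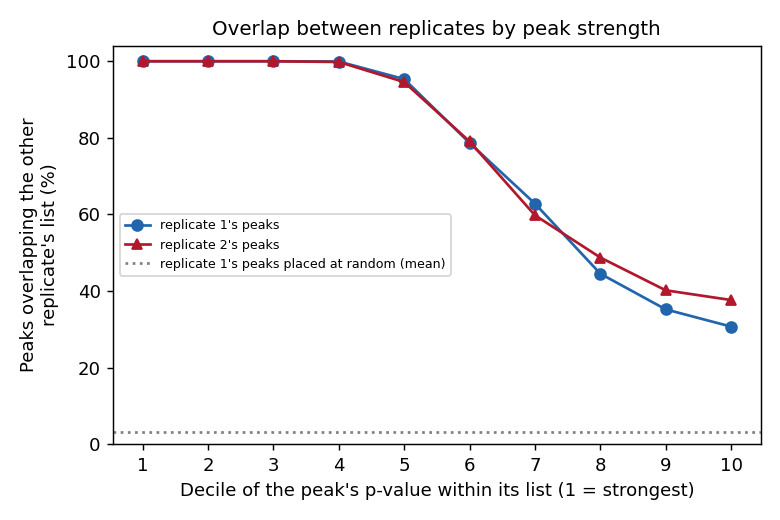
Share of each replicate's peaks that overlap the other replicate's list, in percent, by decile of the peak's p-value within its own list (1 is the strongest). Circles are replicate 1, triangles replicate 2, and the dotted line is the mean for replicate 1's peaks placed at random (3.14%). Shares are 100% in the strongest decile of both lists and 30.7% and 37.7% in the weakest.

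The replicated list kept 68.8% of the pooled peaks, which held 90.6% of the pooled bp. The peaks kept had a median width of 847 bp and a median fold enrichment of 9.29. The 18749 peaks left out had 230 bp and 3.02. Of those kept, 91.1% overlapped a peak in each replicate's own list, as did 1.06% of those left out.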

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

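The lists of replicate 1, replicate 2 and both pooled held 13, 14 and 15 peaks on sequences outside the assembled chromosomes. The replicated list held 12 such peaks, flagged because no comparison used them. The most significant of them, on the unplaced sequence JH584304 from 59441 to 60838, had a −log10 q of 127 and a fold enrichment of 4.96, while the 4020 peaks of the list with a −log10 q at least as high had a median fold enrichment of 30.3 and 0 of them a lower one.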

How the results depend on the processing

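All alternatives reported here were planned. The Jaccard index of the replicates, the promoter excess of peaks and the intestine against other organ odds ratio (3.93 to 5.69 over all alternatives) kept their direction and passed their tests throughout. Overlap shares depended on the peaks compared. For replicate 1 and replicate 2 they were 58.6% and 54.7% with a reciprocal overlap of 50%, 88.2% and 89.7% with a −log10 q of at least 5, and 91.8% and 94.96% for the 20000 strongest peaks. The rank correlation was 0.923 on −log10 p and 0.816 with a −log10 q of at least 5, which also raised the replicated share of pooled peaks to 95.9%. The share of genes with a promoter peak was 67.9% within 500 bp, 69.7% within 2500 bp, 69.8% with the pooled list, 68.0% with a −log10 q of at least 5, 64.9% with 1 TSS per gene, and 69.1% in the own list of either replicate. With matching on CpG ratio 3 lists above and 2 below kept their call for promoter peaks, and enterocyte genes gained one. For covered bp 2 of the 4 narrower lists kept theirs. CpG-rich promoters carried the mark far more often, so matching raised the share expected of CpG-rich lists. For covered bp the cause was not tested.

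Differences that changed sign belonged to lists that had not passed the test, and the cause was not tested. In percentage points of promoters with a peak, the new values were 6.81 (goblet and Paneth), 4.42 (mesothelial) and −6.48 (brain) with CpG matching, −6.53 (enteroendocrine and tuft) and −1.22 (endothelial) with 1 TSS per gene, and 0.250 (mesothelial) with the pooled list. The mesothelial difference ran from −9.10 to 0.903 over single replicates. For covered bp they were −693 bp (goblet and Paneth) with a 2500 bp window, −49.0 bp (interstitial cells of Cajal), 629 bp (erythroid), 60.9 bp (brain) and −327 bp (lung) with a 10000 bp window, and 260 bp (endothelial) with the pooled list. Over single replicates the goblet and Paneth difference ran from −28.4 to 410 bp and the enteric nervous system one from −602 to 139 bp. For distal peaks per gene they were −0.0153 (enteroendocrine and tuft) over 5000 bp, −0.347 (interstitial cells of Cajal) and −0.0796 (cell cycle) within 50000 bp, 0.0705 (liver) within 500000 bp, −0.0635 (interstitial cells of Cajal) and −0.0320 (pancreas) with a −log10 q of at least 5, and −0.00758 (cell cycle) with joined peaks. Over single replicates they ran from −0.0727 to 0.0373 for enteroendocrine and tuft, −0.229 to 0.694 for interstitial cells of Cajal, −0.0502 to 0.000379 for cell cycle, −0.0116 to 0.251 for cardiac muscle and 0.141 to 0.197 for lung. Read depth was not known, and the effect of depth on weak peaks was not tested.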

Other observations

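Beyond the fixed lists, 11 gene families were picked by name after the list results, and values of some of their members, had been seen. Their tests were thus chosen after results were seen, and the p-values are exploratory. The immediate early genes, which respond rapidly to stimulation, were picked after the strong peak at Egr1 was seen, so no p is given for them. All 17 had a promoter peak, with a median of 4379 bp covered. The other 10 families differed from other genes in promoter peaks before any matching (Fisher's exact test, adjusted p at most 0.0234). Ribosomal protein genes had one in 80 of 83 cases, solute carrier genes in 291 of 361, collagen genes in 38 of 44, zinc finger genes in 317 of 365, Fox genes in 37 of 44 and Sox genes in 18 of 19. Keratin genes had 12 of 53, cytochrome P450 genes 31 of 94, defensin genes 0 of 64 and vomeronasal receptor genes 1 of 326. With matching on CpG ratio, collagen genes (86.4% against 69.9%; adjusted p = 0.00843, permutation test), solute carrier genes (80.6% against 76.0%; adjusted p = 0.00843) and zinc finger genes (86.8% against 80.4%; adjusted p = 0.00549) lay above. Keratin genes (22.6% against 48.2%; adjusted p = 0.0011, permutation test), defensin genes (against 19.6%; adjusted p = 0.0011) and vomeronasal receptor genes (against 11.6%; adjusted p = 0.00549) lay below. Ribosomal protein, Fox, Sox and cytochrome P450 genes did not pass with this matching (adjusted p = 0.636, 0.326, 1.0 and 0.573, permutation test). Ribosomal protein genes had more covered bp than random lists (2852 against 2333 bp; adjusted p = 0.0054, permutation test), which were not matched on gene density. Zinc finger genes (1966 against 2327 bp; adjusted p = 0.00599, permutation test) and cytochrome P450 genes (1833 against 2345 bp; adjusted p = 0.0463) were narrower, and solute carrier, collagen, keratin, Fox and Sox genes did not pass. Of the families tested for fold enrichment at the promoter, only zinc finger genes passed, with 18.7 against 20.2 (adjusted p = 0.0360, permutation test).

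The widest peak without a protein-coding TSS covered 11999 bp on chromosome 18 from 61653672 to 61665670. It lay over the lincRNA gene Carmn (61649625 to 61665537, minus strand), known for its role in cardiac and smooth muscle, and included its TSS. It was the second widest peak of the list, ahead of those at Ptch1 (11406 bp), Tpm1 (10532 bp) and Tbx2 (9948 bp). The strongest peak by fold enrichment, 56.6, lay at the immediate early gene Egr1 on chromosome 18 from 34859175 to 34863364.

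The study has 1 group, so no biological explanation that rests on a comparison of groups was tested.

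Some distal peaks were as strong as those at promoters, and 2 of the 10 strongest peaks of the list were distal. The 100 strongest distal peaks were tested as a set. Promoters of annotated non-coding genes would explain most of them only if at least 50% lay near such a TSS, but 14.0% of the 100 had a non-coding TSS within 1000 bp of the summit (exact 95% interval 7.87 to 22.4), against 6.42% of the other distal peaks. CpG-rich DNA remains a candidate explanation, since the median CpG ratio around the 100 summits was 0.732 against 0.319 around the other distal summits. Unannotated start sites were not tested.

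Brain genes, as a list of another organ, had a promoter peak in 20 of 24 cases. Random lists matched on promoter CpG ratio had one in 89.8% on average, and the brain list lay at percentile 4.01 among them. CpG-rich promoters may therefore account for the share, which was not above that of matched lists. A contribution of enteric neurons stays open and was not tested.

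Posterior Hox genes other than Hoxa10 had few covered bp, and groups 10 to 13 had a lower median covered length than groups 1 to 9 in each of the 4 clusters. No test of the difference is given, since the groups were split after it was seen and neighbouring windows overlap, which makes such a test void. Whether a shortage of CpG at posterior promoters plays a part is not decided by the values below. The ratio was taken at 1 TSS per gene, from its gene record, whereas covered bp used the TSS with the most. The record of Hoxc5 (ratio 0.587) starts at 102967443, close to that of Hoxc10 at 102966796. Over the 4 clusters together the median ratio was 0.648 in groups 10 to 13 and 0.587 in groups 1 to 9. Taking off the linear effect of the CpG ratio left 92.9% of the difference in mean covered bp (4792 bp). Since the median ratio was not lower in groups 10 to 13, that step could hardly have shrunk the difference. By cluster, the median ratio was higher in groups 10 to 13 than in groups 1 to 9 in A (0.799 against 0.552) and C (0.673 against 0.477). It was lower in B (0.389 against 0.556) and D (0.5815 against 0.705). That the difference follows the position of the intestine along the body axis is a hypothesis and stays open, since tissue from other positions was not analysed.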
